A study of Xenopus laevis with 4 samples.

How the data were processed

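Total RNA (100 ng per sample) from whole stage 12 embryos was labelled by a 2-cycle protocol and hybridised to the Affymetrix Xenopus laevis genome array, 2 arrays per injection, per the labels' protocols. The deposited values are linear signal intensities per probe set; they come from MAS5 and GCOS 1.4, per the submitters' processing notes and the series text, and no detection calls were used here. The 2% trimmed mean of the 15611 signals was 500.06 in control 1 and 500.05 in the other arrays, so the deposited signals had been scaled per array. Median signals were 164, 167, 161 and 174 for control 1, xSGK1 1, control 2 and xSGK1 2, and 9020, 9049, 9051 and 9183 probe sets reached a signal of 100. The 3' to 5' signal ratio of the beta-actin control probe sets was 3.11, 3.38, 2.24 and 2.06 in that order, and that of GAPDH 16.6, 17.7, 16.4 and 15.6.

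Signals were scaled to a 2% trimmed mean of 500 and taken as log2(signal + 16). The 120 control probe sets and those with a mean scaled signal under 100 were left out, which kept 9251. Of all probe sets 9304 had 1 gene symbol in the platform annotation, 195 several and 6112 none; 9227 of those with 1 gene were matched by gene identifier to the RefSeq table of assembly Xenopus_laevis_v10.1, which changed 2 symbols. No build is named for the array, so no coordinates are given. The suffixes .L and .S mark the homeologous gene copies of this species, whose transcripts can cross-hybridise.

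Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over 9251 probe sets and a threshold of 0.05. The replicate number was read as the experiment number, since the series text describes 2 independent experiments that each held both injections, and the difference control 1 minus control 2 correlated with xSGK1 1 minus xSGK1 2 across probe sets (Pearson 0.838, against a minimum of 0.1). The fit without a block was laid down as the main one, and the fit with the experiment as a block as its alternative; because the numbers pair the arrays and the block changes most calls, both are given. Separate embryo batches are described only as independent experiments. The limma p-values thus rest on 2 of them and on variances moderated across probe sets. With the block they measure how far the injection difference varied between the 2 experiments. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333.

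The design, the named-gene rule, 20 gene lists and most alternatives were fixed before the data were examined. Named genes were those of the complex and of BMP2, BMP4, BMP7 and SGK1, the 12 largest rises and falls past the threshold with both xSGK1 arrays on 1 side of both controls (filled by smallest unadjusted p where fewer passed without the block, as happened for all 24), and up to 4 members per list with the largest moderated statistic; members outside this rule that are named in a count were chosen after their values were seen. A gene with several probe sets was represented in lists by the brightest. Lists of at least 5 measured members, 19 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction. At the preset correlation camera sets a list's genes against all other genes. Those p-values therefore do not measure the spread between embryo batches. With the preset correlation 9 lists were called, the same 9 with the block, and 0 with an estimated correlation or fry. Those last tests rest on the residual spread of a fit to very few arrays, so they have little power. Without the block that spread also holds the difference between the experiments. A call lost in them therefore does not tell an absent shift from too few arrays.

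Scripts were tested on simulated data of 9251 probe sets with 200 changed per run over 5 runs. The fit without the block recovered 0% of 4-fold changes. The fit with it recovered 12% of 1.5-fold, 69.2% of 2-fold and 98.4% of 3-fold and 4-fold changes, and 8.553% of its calls were false. The simulated errors were independent between probe sets. Real arrays can share errors across many probe sets, so these rates need not hold for the real calls. Alternatives were other offsets, filters, normalizations, variance models and list tests, the block, and each array left out in turn; the block combined with other settings was added after seeing the data. Figures were drawn with matplotlib 3.10.9.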

Results

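Whole Xenopus laevis embryos were profiled at stage 12, in gastrulation, on 4 one-colour Affymetrix arrays. Embryos had been injected at the 4-cell stage with 80 ng of a control morpholino or with 40 ng of each of 2 morpholinos against xSGK1, the Xenopus form of SGK1, a serine/threonine kinase of the PI3K pathway. Morpholinos are antisense oligonucleotides that block the translation or splicing of a transcript. Each of 2 independent experiments gave 1 array per injection, so n = 2 per group. The number of arrays limits the precision. The question was which transcripts depend on SGK1 in the gastrula. The study's title names components of the death-inducing signalling complex, the receptor-bound complex that starts caspase activation. Signals below are the deposited signals scaled to a trimmed mean of 500, given as mean ± SD with n = 2. A log2 change is that of signal + 16, xSGK1 minus control morpholino, which understates changes of dim genes. The transcript of the target itself, sgk1.L, measured 2580 ± 367 with the control morpholino and 3185 ± 162 with the xSGK1 morpholinos. Its limma adjusted p was 0.999, and 0.126 with the experiment as a block. A morpholino need not alter the amount of its target transcript, so this reading does not check the knockdown.

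The genes named first were chosen by the smallest unadjusted p of the fit without a block, which favours genes with similar levels in both arrays of a group. The signal of gfpt2.L, an enzyme at the entry of the hexosamine pathway, was 5146 ± 425 in controls and 1232 ± 184 after xSGK1 morpholinos (log2 change -2.05 ± 0.11 SE). Another probe set of this gene gave -2.41. The transcription factor gene creb1.S went from 508 ± 14.6 to 1911 ± 167 (log2 change 1.88 ± 0.14 SE). The replication licensing gene cdc6.S went from 875 ± 78.3 to 3823 ± 1126 (log2 change 2.08 ± 0.15 SE). These SEs, and all calls of single probe sets below, come from the limma fit with the experiment as a block, whereas the camera p-values of lists come from the fit without it. In the blocked fit 740 of 9251 probe sets passed an adjusted p of 0.05, 378 of them higher and 362 lower. The limma fit without that block, the one laid down for this design, called 0 probe sets. Its smallest adjusted p was 0.999, and 334 probe sets (3.61%) had an unadjusted p under 0.05, fewer than that threshold gives by chance. Without the block the residual spread also holds the difference between the experiments, so this low share is no evidence that effects are absent.

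The 12 named upward probe sets, those with the smallest unadjusted p without the block, all rose with the block. Besides cdc6.S they held its homeolog cdc6.L (2394 ± 47.4 and 4879 ± 22.2), the histone gene h2ac7.L (522 ± 53.2 and 1412 ± 186) and cdca9.S (810 ± 59.1 and 1897 ± 167). Also among them was atad3a.L, a mitochondrial ATPase (236 ± 68.1 and 940 ± 376). The small GTPase gene rasd1 rose from 145 ± 6.15 to 597 ± 166. The claudin cldn6.2.S, a tight junction protein, rose from 3485 ± 340 to 7403 ± 843. The maternally supplied growth factor gene gdf1.S rose from 850 ± 31.1 to 1711 ± 1.40. The remaining ones were uchl3.L, sesn1.L, rpn2.S and creb1.S. The 12 downward ones, which all fell with the block, held both gfpt2.L probe sets, the beta-tubulin gene tubb.L (2606 ± 57.8 and 1231 ± 11.5) and impdh2.L of guanine nucleotide synthesis (3265 ± 26.1 and 1575 ± 159). They also held the selenoprotein gene selenok.S (1766 ± 106 and 713 ± 85.9) and rbm45.S (1078 ± 472 and 237 ± 31.8). The others were palm.L, zhx3.L, hnrnpu.S, trappc1.L, rpf2.S and the keratin gene krt8.1.S. Of hnrnpu.S, 3 other and brighter probe sets had log2 changes of -0.13, -0.14 and -0.03 and did not pass with the block (adjusted p = 0.32, 0.341 and 0.878). A second, dimmer h2ac7.L probe set (0.52, adjusted p = 0.175) did not pass either. Across these 24 probe sets the adjusted p with the block ran from 0.0134 for gfpt2.L to 0.0317 for hnrnpu.S. Without the block none passed. The genes rbm45.S, atad3a.L, palm.L and zhx3.L differed between the experiments too, by 0.58, 0.69, -0.92 and 0.51 on the log2 scale (experiment 2 minus experiment 1).

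**Figure D1:**
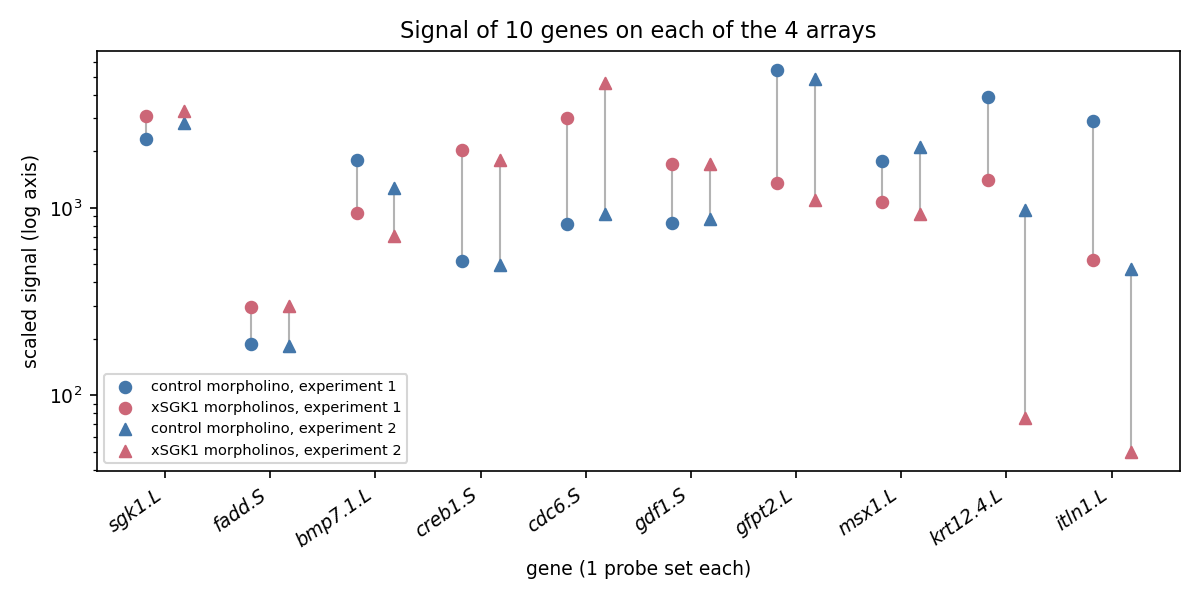
Scaled signal (log axis) of 10 genes on each of the 4 arrays, circles for experiment 1 and triangles for experiment 2, blue for the control morpholino and red for the xSGK1 morpholinos, with a grey line joining the arrays of 1 experiment. The creb1.S, cdc6.S and gfpt2.L signals differ by injection with little difference between the control arrays, whereas krt12.4.L and itln1.L are also lower in the control array of experiment 2 (974 and 471) than in that of experiment 1 (3922 and 2914).

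Of the genes of the death-inducing signalling complex and its receptors, 3 measured members cleared the signal filter. The adaptor fadd.S stood at 186 ± 3.75 in control and 297 ± 3.25 in xSGK1 embryos, 1.52-fold and 1.58-fold in the 2 experiments (log2 change 0.63 ± 0.17 SE). Its limma adjusted p was 0.999 without and 0.0726 with the block, and it passed with the block only when adjusted over the list alone (0.0287). The adaptor tradd.L (153 ± 15.3 and 207 ± 37.1) and the initiator caspase casp10.L (223 ± 253 and 144 ± 155) passed neither way. The casp10.L signal differed far more between the experiments (2.61 on the log2 scale) than between injections (-0.45). Its homeolog casp10.S had a mean under the signal filter, at 76.0 ± 22.6 against 116 ± 34.4. The casp8.L probe set gave signals of 6.90 ± 1.98 and 8.85 ± 2.19, too dim to compare. A list with 3 members is too small for a list test here. With no signal filter the list had a median of 0.24 and was not called (camera adjusted p = 0.0571). Since it follows the study's title its direction is not independent evidence.

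Genes of BMP signalling, which patterns ventral tissue and epidermis, were lower as a group in xSGK1 embryos. The list of 25 ligands, antagonists and pathway members was lower by camera (median log2 change -0.18, adjusted p = 0.00594, and adjusted p = 0.723 with an estimated correlation). The test with an estimated correlation, given here and below, has little power with so few arrays and does not decide a call. Of the list's members 3 fell and 0 rose with the block over all probe sets (2 rose and 6 fell adjusted over the list alone), while 0 passed without the block. The ligand gene bmp7.1.L fell from 1529 ± 368 to 822 ± 165 (log2 change -0.88 ± 0.13 SE, limma adjusted p = 0.0264 with and 0.999 without the block). A protease gene whose product cleaves Chordin, tll1.S, fell from 724 ± 177 to 275 ± 46.4. The related bmp7.2.L (5611 ± 2667 and 4708 ± 1028), bmp4.S (797 ± 42.0 and 489 ± 223), bmp2.L (285 ± 34.5 and 268 ± 144) and bmp2.S (148 ± 29.9 and 135 ± 24.1) did not pass. The 27 BMP target genes were lower too (median -0.28, adjusted p = 0.000156, and adjusted p = 0.723 with an estimated correlation). With the block 5 fell and 0 rose (11 and 0 adjusted over the list alone). They were msx1.L (1941 ± 229 to 1001 ± 109), tbx3.S (467 ± 237 to 174 ± 23.8), evx1.L, szl.L and gata3.S. The target list was also lower in experiment 2 than in experiment 1, by a median of -0.53. Of the called targets szl.L, gata3.S, tbx3.S and evx1.L differed there by -1.86, -1.75, -0.65 and -0.61, and only msx1.L differed little (0.01). With probe sets that carry a cross-hybridising suffix left out, the median of the target list was -0.592. The pathway list lost its call with a signal filter of 300 (adjusted p = 0.105).

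Mesodermal and ectodermal genes were lower as groups too, but the lists share members, so these are not separate findings throughout. The fixed BMP target and epidermal lists both hold msx1, gata2, gata3, dlx3, dlx5 and tfap2a. The BMP target and pan-mesoderm lists both hold szl, evx1 and ventx1.2. Other lists overlap as well. In the pan-mesoderm and ventral mesoderm list 10 of 39 members fell with the block and 0 rose (19 and 6 adjusted over the list alone), among them hes5.1.L (780 ± 244 to 336 ± 125), cdx4.L (360 ± 62.7 to 192 ± 73.5), foxf1.L and tbx6.L. The list's median was -0.48 (camera adjusted p = 0.000122, and adjusted p = 0.723 with an estimated correlation). Between experiments its median was -0.32. In the epidermal list 10 of 39 members fell and 4 rose (12 and 5 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0152, and adjusted p = 0.723 with an estimated correlation). The epidermal keratin gene krt12.4.L measured 3922 and 974 in the control arrays of experiments 1 and 2, and 1402 and 75.4 in the xSGK1 arrays. The secreted lectin gene itln1.L had group means of 1692 ± 1728 and 290 ± 339. Between injections krt12.4.L and itln1.L fell by 2.46 and 2.65 on the log2 scale, and between experiments the differences were -2.97 and -2.82. These 2 genes were singled out after their values were seen. The 4 epidermal members that rose were cldn6.2.S, cldn6.2.L, cldn6.1.L and mal2.S, whose differences between experiments were -0.22, -0.76, -0.44 and 1.14. The epidermal list was itself lower in experiment 2, by a median of -0.28.

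The neural list (36 members, median -0.23, adjusted p = 0.00594, and adjusted p = 0.811 with an estimated correlation) had 0 members past the threshold. Its median was 0.01 in experiment 1 and -0.60 in experiment 2. The organizer and dorsal mesoderm list behaved likewise (21 members, median -0.19, adjusted p = 0.00594, and adjusted p = 0.723 with an estimated correlation). Its median was 0.10 and -0.61 in the 2 experiments, and its only called member was the protocadherin gene pcdh8.2.L (2598 ± 130 to 1673 ± 305). The WNT list was lower (30 members, median -0.24, adjusted p = 0.00279, and adjusted p = 0.723 with an estimated correlation). Its median was -0.06 in experiment 1 and -0.32 in experiment 2. In it fzd10.S, sfrp1.L and cdx4.L fell. With 1 array left out the WNT median ran from -0.421 to 0.0586, that of the organizer list from -0.478 to -0.0624 and the neural one from -0.56 to 0.116, in each case from the fit without the xSGK1 array of experiment 1 to that without the xSGK1 array of experiment 2. Between experiments the neural and WNT lists were lower in experiment 2 by medians of -0.33 and -0.33, and the organizer list by -0.20. The epidermal call ended under quantile (adjusted p = 0.0935) and cyclic loess normalization (0.0755), and the pan-mesoderm and neural calls with a signal filter of 300 (0.0692 and 0.105).

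Ribosomal protein genes were lower and maternal genes higher. Of 70 ribosomal protein genes 67 were lower in both experiments, with medians of -0.27 and -0.31 (camera adjusted p = 9.52e-11, and adjusted p = 0.723 with an estimated correlation). With the block 6 fell (12 adjusted over the list alone), such as rpsa.S (4005 ± 528 to 2608 ± 19.4) and rpl35a.S (8053 ± 1063 to 5859 ± 1118), of which 2 other probe sets did not pass (-0.38 and -0.14, adjusted p = 0.0694 and 0.615). The same genes were lower in experiment 2 than in experiment 1 by a median of -0.52. Of 32 maternal and germ plasm genes 6 rose with the block and 0 fell (12 and 0 adjusted over the list alone). The median was 0.40 (adjusted p = 0.00279, and adjusted p = 0.723 with an estimated correlation). The 6 were gdf1.S, bicc1.S (250 ± 15.9 to 430 ± 5.66), ccnb1.S (640 ± 165 to 1497 ± 533), plin2.S (1152 ± 527 to 2218 ± 716), mos.L and ybx2.L. A dimmer mos.L probe set (0.58) did not pass (adjusted p = 0.144). This list was higher in experiment 2 by a median of 0.35. These medians depended on single arrays. The ribosomal one was -0.0146 without the xSGK1 array and -0.546 without the control array of experiment 2, -0.07 without the control array and -0.552 without the xSGK1 array of experiment 1. In the same order the maternal one was 0.215, 0.677, 0.134 and 0.539. With 1 array left out the pan-mesoderm median ran from -0.666 to -0.0558, that of the BMP targets from -0.712 to -0.136 and the epidermal one from -0.354 to -0.0225. Leaving out the xSGK1 array of experiment 2 ended all 9 list calls, and leaving out the control array of experiment 1 left 4.

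**Figure D2:**
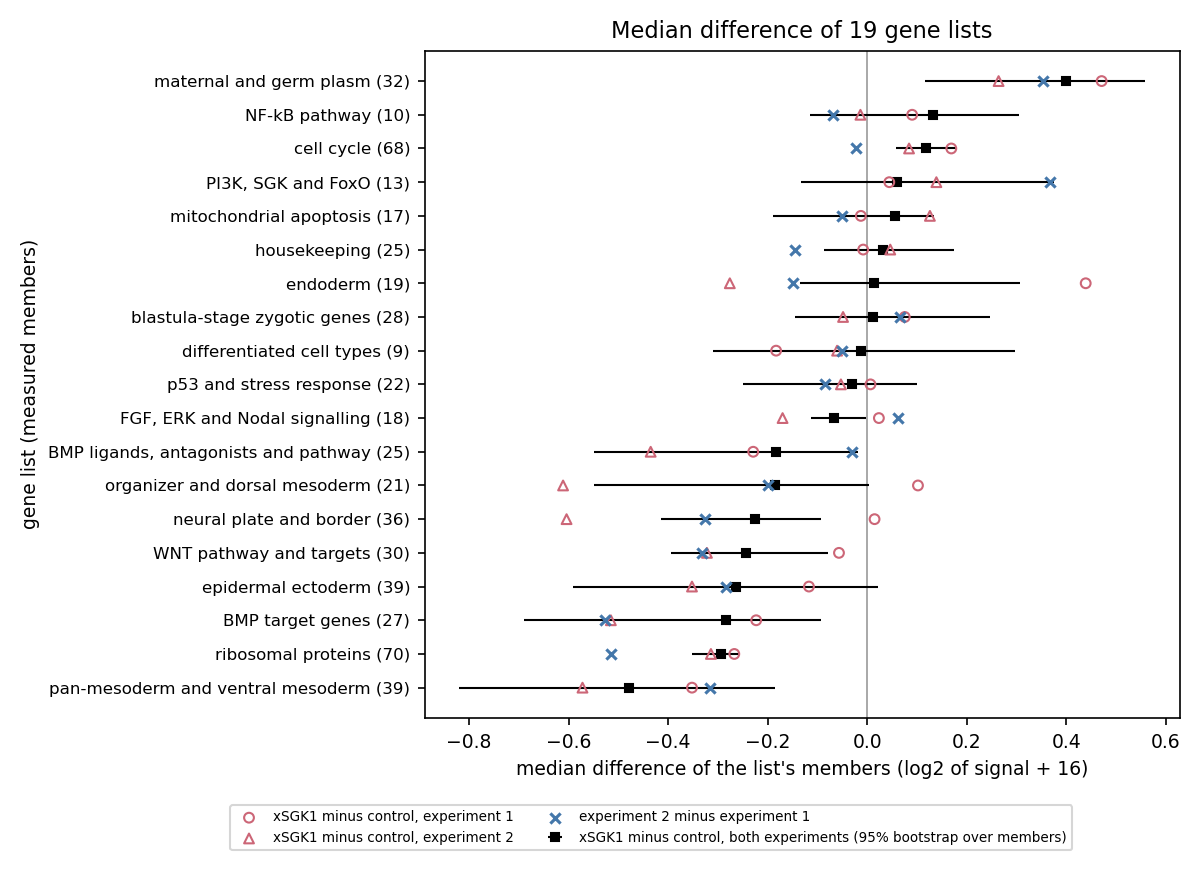
Median log2 difference over the members of each of 19 gene lists (number of measured members in parentheses), as black squares with 95% bootstrap intervals over members for xSGK1 minus control, red circles and triangles for experiments 1 and 2 alone, and blue crosses for experiment 2 minus experiment 1. The pan-mesoderm list has the lowest median (-0.48) and the maternal list the highest (0.40), and in both the cross lies on the same side of 0 as the square.

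The other lists were not called. Among cell cycle genes (68 members, median 0.12, camera adjusted p = 0.166) cdc6.S, cdc6.L, ccnb1.S and ccna1.L rose while cdc20.L (3201 ± 1006 to 1445 ± 224) and mcm3.L fell. In the mitochondrial apoptosis list (17 members, adjusted p = 0.776) birc5.L, which encodes the caspase inhibitor and mitotic protein survivin, rose from 548 ± 227 to 1224 ± 304, and pdcd4.S fell from 744 ± 218 to 362 ± 107. The list's median was 0.06 while its mean was -0.03 and the test pointed down. In the p53 and stress list (22 members, adjusted p = 0.953) the p53 target genes sesn1.L (83.3 ± 17.8 to 372 ± 213) and ppm1d.L (914 ± 140 to 1663 ± 14.9) rose, the latter by 1 of its 2 probe sets (the other 0.48, adjusted p = 0.153). The list had a median of -0.03, a mean of 0.10 and a test that pointed down. Among PI3K, SGK and FoxO genes (13 members, adjusted p = 0.414) creb1.S rose and the sodium channel subunit gene scnn1a.L fell from 707 ± 23.6 to 420 ± 0.63. The endoderm list (19 members, adjusted p = 0.953) had a median of 0.01 with a test that pointed down, and a2m.S fell in it. The experiments differed in sign, with medians of 0.44 in experiment 1 and -0.28 in experiment 2. Blastula-stage genes (28 members, adjusted p = 0.953) held 1 rise, pou5f3.3.L, and 1 fall, gs17.L (1666 ± 1001 to 585 ± 467). The NF-kB (10 members, adjusted p = 0.868), FGF, ERK and Nodal (18 members, adjusted p = 0.536), differentiated cell type (9 members, adjusted p = 0.414) and housekeeping lists (25 members, adjusted p = 0.734) were not called either. In the differentiated cell type list the median (-0.01) and the mean (0.000777) differed in sign. In the housekeeping list h4c4.L rose and tubb.L fell.

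The 2 experiments gave similar ratios of xSGK1 to control signal, and they also differed from each other. Across probe sets, which are not independent replicates, the log2 ratios of experiments 1 and 2 had a Pearson correlation of 0.666 and a Spearman correlation of 0.626. At least 2-fold in the same direction in both were 217 probe sets, 104 higher and 113 lower, with gfpt2.L, creb1.S, cdc6.S and palm.L among them. Between the experiments 791 probe sets differed at least 2-fold in the same direction with both injections (Pearson 0.838), and limma called 3775 with the injection as a block. The injection and experiment contrasts, which independent errors of equal size would leave uncorrelated, had a Pearson correlation of 0.471. Larger deviations in the control 1 and xSGK1 2 arrays than in the others would not leave them so. Those arrays were the least alike pair (Pearson 0.799, against 0.887 to 0.955 for the other pairs). Of the 740 probe sets called for injection 472 were also called between the experiments, 435 of them in the same direction, where 151 would be shared by independent lists. The other 268 were not, as with creb1.S, cdc6.L and gfpt2.L.

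**Figure D3:**
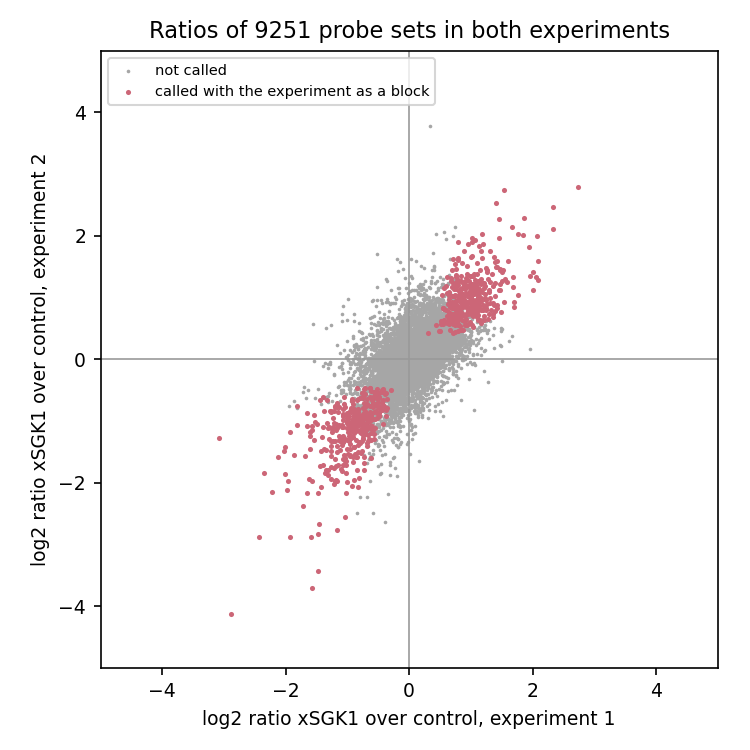
Log2 ratio of xSGK1 to control signal for each of 9251 probe sets in experiment 1 (horizontal axis) and experiment 2 (vertical axis), with the 740 probe sets called with the experiment as a block in red and the others in grey. The Pearson correlation across probe sets is 0.666.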

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

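The test of this part was chosen after the values were seen. The control probe set AFFX-r2-Ec-bioB-M_at, a hybridisation spike-in outside the comparisons, had a mean signal 1.27 times as high in the xSGK1 arrays (235 and 229) as in the control arrays (187 and 179). It drew attention because both xSGK1 arrays lay above both controls. Of 26 control probe sets with a mean signal of at least 100 it was the only 1, where chance placement gives 4.3. That 4.3 treats the arrays as exchangeable and the probe sets as independent. Yet the BioC 3' spike-in gave 139, 143, 519 and 394 in control 1, xSGK1 1, control 2 and xSGK1 2. The BioDn 3' spike-in gave 1562, 1614, 1644 and 1737 in that order. A technical part of the difference between the experiments is therefore not excluded.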

How the results depend on the processing

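Without a block, the count of 0 called probe sets held under every other offset, filter, normalization and variance model tried. It became 740 with the replicate block, 217 by the rule of at least 2-fold in both experiments, and 0 to 110 with 1 array left out (110 without xSGK1 replicate 1, 7 without xSGK1 replicate 2). In such fits the lone array is assumed to vary like the others. The blocked count, in combinations chosen after seeing the data, was 1136 with offset 64, 490 with a signal filter of 300, 1392 with cyclic loess, and 355 with at least 2-fold. The 9 list calls became 0 with an estimated correlation and 0 with fry, and 0 to 9 with 1 array left out (4 without control replicate 1, 0 without xSGK1 replicate 2). Without xSGK1 replicate 2 the neural list turned upward (adjusted p = 0.63, range 3.32e-06 to 0.63 with 1 array left out). The block changed no list call. The correlation of 0.666 between experiments was 0.508 with no filter, 0.685 with a filter of 300 and 0.628 with quantile normalization, and the 217 probe sets became 99 with offset 64 and 112 with a filter of 300. Of 97 named probe sets 50 passed with the block, and signs differed in 10 of 1326 values, all in fits with 1 array left out. The cause was not tested, beyond the fewer arrays or probe sets of those fits. Signals near background, such as those of casp8.L, cannot be compared.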

Other observations

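Tests in this part were chosen after the values were seen, including the 14 gene families, whose membership was corrected after a first run; only the criterion for the correlation after normalization was set before the result. Genes of ribosome assembly in the nucleolus were lower in xSGK1 embryos beside the ribosomal proteins: of 41 members 3 fell with the block, nop16.S (2654 ± 1069 to 1317 ± 789, n = 2), dkc1.L (3911 ± 1266 to 2482 ± 1033) and rpf2.S, and 0 rose (median log2 change -0.11, camera adjusted p = 0.0389 over 14 families, and adjusted p = 0.582 with an estimated correlation). A dimmer dkc1.L probe set (-0.20) did not pass (adjusted p = 0.535). With the block 740 of all 9251 probe sets were called, 362 of them lower, so so few called members do not by themselves set this family or the next apart. Splicing and hnRNP genes were lower by a smaller amount (55 members, median -0.08, adjusted p = 0.0165, and adjusted p = 0.582 with an estimated correlation), with srsf6.S and sf3b5.S falling. That splicing call ended under quantile (adjusted p = 0.169) and cyclic loess normalization (0.227). Both families were also lower in experiment 2 than in experiment 1, by medians of -0.37 and -0.27. The histone family was not called (17 members, adjusted p = 0.0581), though h4c4.L, h2ac7.L, h2ac14.L and h2ax.lS rose, and neither were the claudins (6 members, adjusted p = 0.0663), of which 3 rose. Both passed under quantile (0.0117 and 0.0117) and cyclic loess normalization (0.0103 and 0.0157), but with an estimated correlation neither did (0.413 each as scaled, 0.475 each under quantile and 0.562 each under cyclic loess normalization). The remaining 10 families were not called.

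The pattern of most interest is that maternal genes were higher and ribosomal protein, epidermal, mesodermal and BMP target genes lower in xSGK1 arrays. It ran along the same axis on which experiment 2 differed from experiment 1. Deviations of the control 1 and xSGK1 2 arrays alone would give such an axis too, and 4 arrays do not tell the 2 apart. Intensity-dependent scaling as the cause of that shared axis is argued against, since the correlation of both contrasts was 0.471 before and 0.47 after cyclic loess normalization (0.421 after quantile normalization). As the whole cause of the maternal, ribosomal, pan-mesoderm and BMP target shifts it is argued against too: all 4 lists stayed called after cyclic loess at the preset correlation of 0.01, with 95% bootstrap intervals over members on the same side of 0, and the median nearest 0 was the ribosomal -0.258 (-0.326 to -0.211). With an estimated correlation none of these lists was called even as scaled (adjusted p = 0.723 each), so the argument rests on medians that the normalization left in place, not on the calls, and the intervals treat members as independent. For the epidermal genes it cannot be told apart from a change in the embryos. Their median was -0.263 (-0.592 to 0.0218, adjusted p = 0.0152) before and -0.186 (-0.551 to 0.0575, adjusted p = 0.0755) after cyclic loess, so the interval reached 0 both times, and the call ended as the median moved toward 0. A lower share of ectodermal cells would by itself raise the pan-mesoderm list. Its median was -0.478 (95% bootstrap interval -0.82 to -0.185), and -0.352 and -0.572 in experiments 1 and 2. Such a share alone therefore does not account for the mesodermal fall. That fall is part of the pattern and was known beforehand, so this is no independent test. Without the xSGK1 array of experiment 2 the pan-mesoderm median was -0.0558. The endoderm list, which should have risen too, had medians of 0.439 and -0.276 in experiments 1 and 2, so it rose in experiment 1 only. A candidate explanation is an earlier average stage of the xSGK1 embryos. The skeletal alpha-actin M control probe set was 3.4-fold lower in the xSGK1 array of experiment 1 (599 and 176) and 2.16-fold lower in that of experiment 2 (98.4 and 45.5). That probe set is in no list and was not tested, although the differentiated cell type list names the alpha-actin genes actc1 and acta1. Its array order was that of the krt12 genes. The keratin gene krt8.1.S did not follow that order (6458, 3919, 5818 and 3468 in control 1, xSGK1 1, control 2 and xSGK1 2), nor did its other probe set. The 3' alpha-actin probe set was 6.27-fold lower in experiment 1 and near background in experiment 2. Blastula-stage genes, which also bear on stage, did not move as such a difference would lead one to expect. Their median was 0.0125 (-0.145 to 0.247), with 14 members higher and 14 lower. The 9 measured genes of differentiated cell types had a median of -0.0125 (-0.31 to 0.297), which cannot be read for stage. They include foxi1.L, which is in the blastula-stage list too, where an earlier stage would move it the other way. Medians near 0 over members that go both ways do not exclude an earlier stage. Lost mesoderm would lower the alpha-actin signals too, and the design does not separate a slower development due to the xSGK1 morpholinos from an earlier harvest. Both xSGK1 morpholinos were injected together and no rescue was profiled. Loss of SGK1 is therefore not told apart from other effects of these oligonucleotides either.

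How many of the 740 calls a stage difference would account for stays open. In 43 probe sets of 9251, gfpt2.L, creb1.S, cdc6.S, rasd1, selenok.S and sesn1.L among them, both xSGK1 arrays lay at least 2-fold outside both control arrays, which a steady change along the array order of alpha-actin does not give without error. In 0 probe sets did the crossed pairs (control 1 and xSGK1 2 against control 2 and xSGK1 1) part that far, and by any margin 2784 and 775 did. By injection 16.3% of probe sets parted upward and 13.8% downward, where chance placement gives 16.7% each. That reference treats the arrays as exchangeable, which they were not: the split by experiment gave 378 at least 2-fold and 5692 by any margin. It therefore does not settle whether the 2784 were an excess. Comparing the injection and crossed splits decides nothing, since with error the injection split needs only xSGK1 1 and control 2 to change places and the crossed one needs more. It was the last of 4 criteria tried on this question, each after some of the values were known, and they gave different answers, so none is used as a verdict. Stage-matched embryos would be needed.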
